A study of Homo sapiens with 20 samples.

How the data were processed

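The series holds RNA-seq, ribosome profiling (Ribo-seq) and acetylated RNA immunoprecipitation sequencing (acRIP-seq) of K562 cells in which an exon of NAT10 was deleted with CRISPR-Cas9, and of the parental cells. RNA-seq and Ribo-seq have 2 libraries per genotype, and acRIP-seq has 2 per genotype for each of input, IgG and ac4C antibody. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

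For RNA-seq and Ribo-seq the authors deposited whole-number read counts per gene, and per the file headers these counts were made from alignments with duplicate reads removed. The submitters' processing notes name cutadapt, Trimmomatic, STAR, SAMtools, featureCounts and the build GRCh38.p13, without roles or versions. Total RNA was extracted for RNA-seq and libraries were made with a NEBNext Ultra kit, per the labels' protocols. Cells for Ribo-seq were treated with cycloheximide and ribosome fractions were collected from sucrose gradients, per the same protocols. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. Removing duplicates without molecular identifiers lowers the counts of abundant short transcripts most, and footprints are short. The RNA table covers 60616 gene identifiers, of which 60419 had a symbol in the reference name table, and the footprint table covers 20401 protein-coding identifiers, of which 20352 had one. Copies of genes on the Y pseudoautosomal region (44 and 18 identifiers) were left out.

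Total counts were 18093324 and 18778485 in the knockout RNA-seq libraries and 10388717 and 12725302 in wild type. Ribo-seq totals were 1173526 and 621287 in knockout and 1220308 and 911336 in wild type. Library pairs were compared by a chi-square test over genes with at least 20 summed counts. The knockout RNA-seq pair gave a chi-square of 1.03 per degree of freedom (16613.3 on 16131), which is 2.99% over counting noise, with p = 0.00388 over genes. The wild type RNA-seq pair gave 12.5, the knockout Ribo-seq pair 2.38 and the wild type Ribo-seq pair 2.56. The 2 knockout RNA-seq libraries were therefore treated as 1 sample and their counts summed. The planned fit of 4 RNA-seq libraries was kept as an alternative chosen after seeing the data. With the summed sample the RNA fit had 1 residual degree of freedom, and the lone knockout sample was assumed to vary like wild type.

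Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The biological coefficient of variation was 9.12% for RNA and 12.0% for footprints. Translational efficiency was tested as the interaction of assay and genotype in 1 model of all libraries (3 residual degrees of freedom). In that model the biological coefficient of variation was 7.13%. Log2 fold changes are knockout minus wild type and carry the standard error (SE) of the fit. A fold of a gene with 1 to 3 counts in a genotype is given as the ratio of summed counts with an exact interval (95%), and against 0 counts as a bound from a floor of 3 counts over the genotype. Intervals and floors cover counting error only.

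Fixed before the data were examined were the tests, most of the alternatives, the rule for named genes and 31 gene lists. The lists cover globins, heme synthesis, iron handling, red cell membrane, erythroid regulators, late erythroid genes, markers of megakaryocytes, granulocytes and monocytes, lymphocytes, fibroblasts and epithelium, and stem and progenitor cells, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, tRNA synthetases, amino acid stress, endoplasmic reticulum (ER) stress, heat shock, p53 targets, S phase, mitosis, replication histones, mitochondrially encoded genes, the respiratory chain, glycolysis and hypoxia, cholesterol synthesis, the interferon response, apoptosis, RNA modification, and ABL and JAK signalling. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists. An estimated correlation and fry were alternatives. With an estimated correlation camera uses the residual degrees of freedom of the fit, 1 in RNA, 2 in footprints and 3 in efficiency. Few lists could pass on so few, so a call lost in this way decides little. A camera call compares a list with the other genes, while fry asks whether its members move one way.

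The rule for named genes gave NAT10 first. It then took, per comparison, the 8 largest rises and 8 largest falls among called protein-coding genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the genotypes. It added up to 4 members with the lowest adjusted p from each called list and from the globin, heme, red cell membrane, erythroid regulator and megakaryocyte lists. Always included were, among others, GATA1, KLF1, TAL1, HBG1, HBG2, HBZ, HBE1, TFRC and ALAS2 and the 8 NAT10-dependent acRIP genes with the highest fold enrichment in wild type. Other genes are marked as chosen after their values were seen.

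For acRIP-seq the authors deposited peak lists called on transcript sequences with replicates merged, for ac4C antibody (IP) and IgG each against input, in both genotypes. The fold enrichment (a ratio over input) and the -log10 q value of each peak are the authors' own, as deposited, and were used only within a list. The submitters' processing notes name Bowtie2, MACS2, bedtools and ChIPseeker. Depth is not given in the peak lists. The knockout acRIP libraries carry a protocol text of their own, apart from that of the wild type libraries, so library set and genotype cannot be told apart in this assay. Input and signal tracks were not used here. Overlapping summits of a list were merged into regions, and regions sharing at least 1 base on the same transcript were counted as overlapping. Random placement was estimated from 20 shuffles along each transcript. A wild type IP region that overlaps no wild type IgG region was called IP-specific, and NAT10-dependent when it overlaps no knockout IP region either. These names describe overlap and not a test. Lists among such genes were tested with a two-sided Fisher's exact test, with genes tested in RNA and present in any peak list as background. Set medians in the fits were compared with 10000 random sets matched on mean expression in 20 bins. Shares of regions carry Wilson intervals (95%). These treat regions as independent, although a gene can hold regions on more than 1 transcript, and they cover no spread between libraries. They are too narrow to compare lists.

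The order of genes along chromosomes came from a RefSeq gene table of another patch of the assembly, GRCh38.p14, used only for names and neighbours. The edgeR tests of RNA, footprints and translational efficiency were also run on simulated counts with 200 changed genes. These counts were drawn at the trended dispersion of each fit, with no further spread between genes and no replicate effect. The recovery and the shares of unchanged genes among calls may therefore be optimistic for the real data. In the RNA simulation of 16277 genes, 44.8%, 58.2% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 10.6% of the calls were unchanged genes. For footprints (8887 genes) recovery was 13.4%, 47.8% and 90.9%, with 4.72% unchanged, and for translational efficiency (8821 genes) 14.9%, 53.7% and 90.9%, with 0.935%. In a simulation with no change and 1 knockout culture read as 2 libraries, 18.1% of genes had an unadjusted p under 0.05 with the libraries kept apart and 4.43% with the libraries summed. At the adjusted threshold 0 genes were called in either setting.

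Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, a minimum fold change, removal of the most abundant genes, a replicate block, removal of each library in turn, stricter peak thresholds, a reciprocal overlap of 50% and another enrichment background.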

Results

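K562 is a leukaemia cell line with erythroid and megakaryocytic potential, and NAT10 is the acetyltransferase that makes N4-acetylcytidine (ac4C) in RNA. The series was designed to ask how loss of NAT10 bears on erythroid gene expression, on translation and on mRNA acetylation. RNA-seq and Ribo-seq counts were available for 2 knockout and 2 wild type libraries each, with 10388717 to 18778485 counts per RNA-seq library and 621287 to 1220308 per Ribo-seq library. Peak lists of ac4C immunoprecipitation (IP) and of an IgG control were available for each genotype. The 2 knockout RNA-seq libraries differed by 2.99% over counting noise, against 12.5 times counting noise for the wild type pair, and were counted as 1 sample. RNA comparisons therefore set 1 summed knockout sample against 2 wild type libraries.

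NAT10 (ENSG00000135372.9) was lower in every knockout library. Its RNA-seq counts were 903 and 925 in knockout, or 49.9 and 49.3 CPM (counts scaled to library size), against 1439 and 1837 in wild type, or 139 and 144 CPM. The fold change was -1.51 on the log2 scale (SE 0.085, edgeR quasi-likelihood adjusted p = 0.000102). NAT10 footprints were 55.4 and 48.3 CPM in knockout and 176 and 188 CPM in wild type, with a log2 fold change of -1.82 (SE 0.19, edgeR adjusted p = 0.000334). The counts cover the whole gene and not the deleted exon alone, so residual reads do not measure intact transcript.

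**Figure D1:**
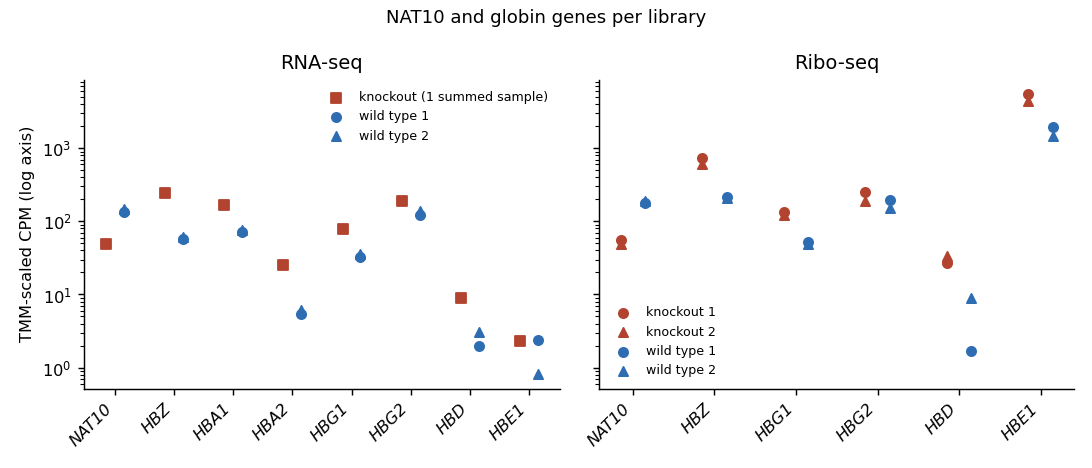
CPM after TMM scaling on a log axis for NAT10 and globin genes in each library, with 1 summed knockout and 2 wild type RNA-seq samples and 2 Ribo-seq libraries per genotype. NAT10 lies lower and HBZ lies higher in knockout in both assays, while HBE1 differs between genotypes in footprints and does not pass the test in RNA.

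Genes beside NAT10 on chromosome 11 were also lower, a comparison made after the values were seen. Of 173 tested protein-coding genes between NAT10 and the short-arm tip, with the beta-globins left out, 106 fell and 2 rose in RNA, and their median log2 fold change was -0.58 (SE 0.029). This share of falls, 61.3%, compares with 10.2% of all other placed genes. The 50 genes next to NAT10 on the other side had a median of -0.10 (SE 0.055), and 6 of them fell. Footprints of 122 genes on the tip side had a median of -0.60 (SE 0.051), of which 27 fell and 1 rose. The 106 protein-coding genes are 7.41% of all 1430 RNA falls, which were counted over all tested genes, non-coding genes included. The 27 genes are 7.85% of all 344 footprint falls. Among genes named by the rule, RPLP2, HBD, HBG1, HBG2, HBE1, CYB5R2, RPL27A, SOX6, RPS13, LDHA, CD59 and LMO2 lie there in the gene order of GRCh38.p14.

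**Figure D2:**
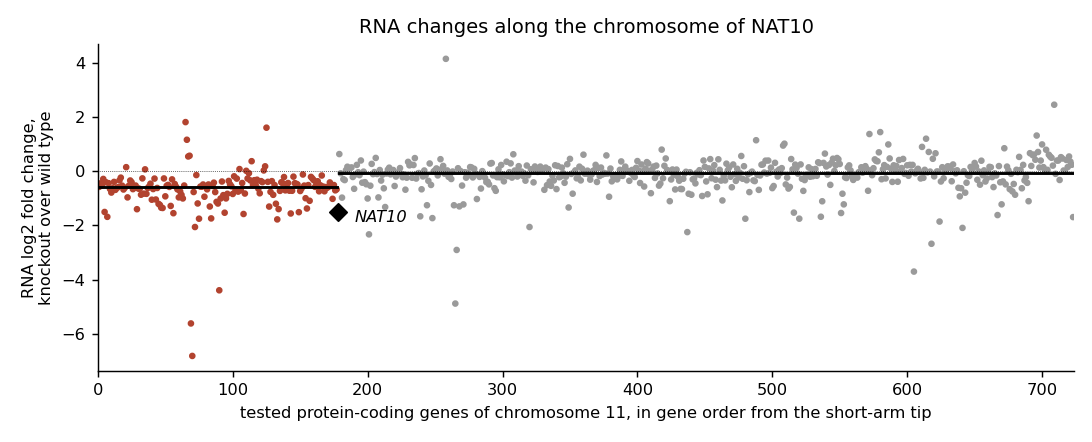
RNA log2 fold change (knockout minus wild type) of 723 tested protein-coding genes of chromosome 11 in gene order, with genes on the tip side of NAT10 in red, the others in grey and NAT10 as a diamond. The lines are medians, at -0.58 on the tip side and -0.04 on the other side.

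Among called protein-coding genes with a mean log2 CPM of at least 3 and no overlap between genotypes, HMGA2, a chromatin-binding protein of fetal and stem cells, rose most, with an RNA log2 fold change of 5.58 (SE 0.17, edgeR adjusted p = 9.18e-06). The growth factor IGF1 rose by 2.32 (SE 0.074), the embryonic alpha-type globin HBZ by 2.05 (SE 0.074) and the fibroblast growth factor family member FGF13 by 2.95 (SE 0.19). PAK6, PCDH9, HBA2 and MAGEB2 rose by 2.32, 2.18, 2.12 and 2.03. In the same class FYB1, an adaptor of immune-cell signalling, fell most, at -5.38 (SE 0.13, edgeR adjusted p = 3.89e-06), followed by the surface glycoprotein CD24 at -3.61 (SE 0.20). RUNX1T1 (-3.52, SE 0.79, at -4.13 against wild type replicate 1 and -2.04 against replicate 2), RRAGD (-3.30), the chemokine receptor CCR4 (-3.21), EDARADD (-3.13), the actin regulator WAS (-2.96) and MS4A4A (-2.91) also fell. In all, 2271 of 16277 tested genes changed (841 rose, 1430 fell). Without a filter on low counts the balance turned, with 1925 up and 1588 down. All 2271 had the same sign against each wild type library, which their selection on these libraries favours, and 78.7% of all tested genes did. With the knockout libraries kept apart the count was 5476, and DESeq2 called 1039, of which 1019 were shared.

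Most globins rose in RNA. Of 8 measured globin genes 6 rose, and 7 did adjusted over the list alone, with a median log2 fold change of 1.17. The camera adjusted p was 5.56e-08, and 0.617 with an estimated correlation. With an estimated correlation camera has 1 degree of freedom in RNA, so few lists could pass it. HBA1 rose by 1.16 (SE 0.070), HBG1 by 1.17 (SE 0.098) and HBG2 by 0.55 (SE 0.084), as did HBZ and HBA2, while HBE1 was at 0.58 (SE 0.52, edgeR adjusted p = 0.517). Globins took 0.0761% and 0.0753% of RNA counts in the knockout libraries and 0.0341% and 0.0345% in wild type. HBG1, HBG2, HBD and HBE1 sit within the lower tip segment of chromosome 11. HBA1 and HBA2, and HBG1 and HBG2, are near-identical pairs whose reads the counting may have split, so the values of single members are uncertain.

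Other erythroid genes moved in both directions. Of 29 red cell membrane genes 7 rose and 4 fell (8 and 4 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0494; adjusted p = 0.617 with an estimated correlation). Among those lower were stomatin STOM (-0.90), the complement inhibitor CD59 (-1.01) and BCAM (-1.47). Of 22 heme synthesis genes 5 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0499; adjusted p = 0.617 with an estimated correlation). Ferrochelatase FECH (0.45) and the iron-sulfur scaffold ISCU (0.49) rose, while biliverdin reductase BLVRA (-0.54) fell. Both camera calls were lost without knockout replicate 2 (adjusted p = 0.0745 for membrane and 0.0897 for heme genes, whose difference from other genes went from 0.14 to 0.089), and the heme call also with RLE scaling (adjusted p = 0.0505).

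Of 27 erythroid regulators 3 rose and 5 fell (5 and 9 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.318). GATA1, the master erythroid transcription factor, fell by 0.42 on the log2 scale (SE 0.090, edgeR adjusted p = 0.0203). TAL1 rose by 0.53 (SE 0.071) and SOX6 by 1.62 (SE 0.17), whereas LMO2 (-0.70) and ETV6 (-0.56) fell. KLF1 (-0.09, SE 0.086), the transferrin receptor TFRC (-0.13, SE 0.083) and the heme enzyme ALAS2 (0.47, SE 0.17) did not pass the test, with edgeR adjusted p values of 0.550, 0.370 and 0.113. Of 23 late erythroid genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.621), and of 15 iron handling genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.297).

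The marker lists of megakaryocytes, of granulocytes and monocytes, and of fibroblasts and epithelium lay below other genes by camera. Of 10 megakaryocyte genes 4 fell (1 rose and 5 fell adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0131; adjusted p = 0.617 with an estimated correlation). The platelet integrin ITGA2B fell by 1.45 on the log2 scale (SE 0.15), F2R by 0.81, the collagen receptor GP6 by 0.56 and the weakly expressed RAB27B by 3.86. Of 13 granulocyte and monocyte genes 6 fell (1 rose and 7 fell adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.00283; adjusted p = 0.617 with an estimated correlation). The Fc receptor FCGR2A fell by 1.38 (SE 0.084), CD33 by 1.11, ITGAM by 1.71 and the myeloid transcription factor SPI1 by 0.68. The median of this list was -1.03 against wild type replicate 1 and -0.58 against wild type replicate 2. Of 6 fibroblast and epithelial genes 2 fell, KRT19 (-0.74) and KRT8 (-0.37), with 4 adjusted over the list alone (camera adjusted p = 0.00581; adjusted p = 0.617 with an estimated correlation), and EPCAM and COL6A3 stood at -0.42 and -1.55 without passing the test. Of 5 lymphocyte genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.126).

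The ER stress list lay below other genes by camera. Of 23 ER stress genes 11 fell (1 rose and 14 fell adjusted over the list alone), with a median of -0.39 (camera adjusted p = 6.64e-06; adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.0437). The disulfide isomerases PDIA3, PDIA4 and PDIA6 stood at -0.80 (SE 0.080), -0.61 and -0.50, and the transcription factor CREB3L2 at -0.66. Cytosolic ribosomal protein genes had a median of -0.20, and 8 of 79 fell (8 adjusted over the list alone; camera adjusted p = 3.37e-06; adjusted p = 0.702 with an estimated correlation). RPS6 (-1.18) and RPL3 (-0.76) fell, as did RPL27A (-0.88) and RPLP2 (-0.65), which lie on the lower segment of chromosome 11. The ribosomal protein median was -0.10 against wild type replicate 1 and -0.31 against wild type replicate 2.

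Of 24 cholesterol synthesis genes 8 rose (12 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 4.20e-05; adjusted p = 0.617 with an estimated correlation). Lanosterol synthase LSS rose by 0.91 (SE 0.074), STARD4 by 0.77, IDI1 by 0.69 and squalene epoxidase SQLE by 0.63. In the respiratory chain 8 of 69 genes rose (8 adjusted over the list alone; median 0.14, camera adjusted p = 3.04e-05; adjusted p = 0.617 with an estimated correlation), among them NDUFB2 (0.55), UQCR10 (0.48), UQCRQ (0.43) and NDUFA6 (0.41). Of 63 mitochondrial ribosomal proteins 7 rose (13 rose and 4 fell adjusted over the list alone; median 0.17, camera adjusted p = 6.55e-05; adjusted p = 0.617 with an estimated correlation), including MRPL21 (0.45), MRPL3 (0.36), MRPS15 (0.36) and MRPL40 (0.29). Of 27 amino acid stress genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 0.00486; adjusted p = 0.617 with an estimated correlation). ATF5 (0.79), PSPH (0.79) and TRIB3 (0.77) rose and PHGDH, the first enzyme of serine synthesis, fell (-0.92). Of 32 mitosis genes CDK1 (0.31) and AURKA (0.27) rose, and 0 did adjusted over the list alone (median 0.08, camera adjusted p = 0.00581; adjusted p = 0.621 with an estimated correlation), with CCNA2 (0.27) and CENPA (0.24) not past the test. Of 54 RNA modification genes ALKBH5 (0.38) and CTU2 (0.40) rose and NAT10 fell (2 and 1 adjusted over the list alone; median 0.09, camera adjusted p = 0.0288; adjusted p = 0.617 with an estimated correlation), with WTAP at 0.18 (edgeR adjusted p = 0.134). AURKA and CTU2 lost their calls without knockout replicate 1.

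In footprints, HMGA2 was again higher, with 39 counts in knockout and 1 in wild type, a ratio of 45.3 (interval 7.66 to 1834). The embryonic globins HBZ and HBE1 rose by 1.66 (SE 0.16) and 1.55 (SE 0.15) on the log2 scale, each with an edgeR adjusted p = 0.000320, and HBD rose by 2.59 (SE 0.53). KCNG2, GBX1 and PCDH10 were higher on few counts, by ratios of 25.5 (4.13 to 1054), 19.7 (5.06 to 170) and 11.2 (3.48 to 57.6). GRIN2B (4.14), ISLR (3.65) and PCDHB3 (3.57) rose, with GRIN2B at 19 and 101 counts in knockout and 4 and 5 in wild type. GBX1, GRIN2B, ISLR and PCDHB3 were not among the genes tested in RNA. KCNG2 was at -1.49 in RNA (edgeR adjusted p = 0.371), while HMGA2, PCDH10 (5.56) and HBD (1.83) rose there too. FYB1 (-5.38, SE 0.46) and PTGS1 (-3.6, SE 0.52) fell. CYB5R2 had 0 counts in knockout and 33 in wild type, at least 9.47-fold lower. CD24, ACE, CCR4, CPXM1 and PRTG were lower in knockout, by ratios of 43.9 (7.54 to 1769), 24.1 (3.99 to 986), 13.5 (4.34 to 67.8), 10.6 (3.36 to 53.9) and 9.90 (2.45 to 86.7).

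Across footprints 475 of 8887 genes changed by edgeR, 131 upward and 344 downward. The count fell to 264 without wild type replicate 1, rose to 716 without knockout replicate 2, and was 181 with DESeq2. A replicate block, which takes same-numbered libraries as pairs, gave 1594. Leaving out wild type replicate 1 ended the calls of KCNG2, GBX1, GRIN2B, ISLR, PCDHB3, PCDH10, HBD and CPXM1. Leaving out wild type replicate 2 ended that of ACE, leaving out knockout replicate 1 that of PRTG, and leaving out knockout replicate 2 those of GRIN2B (then 1.86), PCDHB3 and PRTG. KCNG2, GBX1, ISLR and PCDHB3 had 0 counts in wild type replicate 1, and FYB1, ACE, CCR4 and CPXM1 had 0 in knockout replicate 2, so the size of each value rests on the other library. HBD was at 1.72 without wild type replicate 1 and 4.06 without wild type replicate 2.

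Globin footprints rose for 4 of 6 measured genes (4 adjusted over the list alone), with a median of 1.44 (camera adjusted p = 2.10e-06; adjusted p = 0.459 with an estimated correlation). HBG1 rose by 1.33 (SE 0.20) and HBG2 was at 0.37 (SE 0.19, edgeR adjusted p = 0.285). Globins took 0.691% and 0.556% of footprints in knockout and 0.252% and 0.202% in wild type. HBE1 had a mean log2 CPM of 11.71 in footprints and 1.04 in RNA, so its RNA count is not a measure of its footprint level. Among 23 red cell membrane genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with a camera adjusted p = 0.283. STOM was at -1.24 (SE 0.19) and GYPB and GYPE at 1.95 and 1.79, paralogs that may share reads. GATA1 (-0.48), KLF1 (-0.38), TAL1 (0.72), TFRC (-0.17) and ALAS2 (0.15) did not pass, with edgeR adjusted p values of 0.0588, 0.172, 0.132, 0.590 and 0.879, nor did the regulators GFI1B (-0.58) and STAT5A (-0.37). Of 22 heme synthesis genes SLC25A37 rose (0.77) and BLVRA fell (-0.66), as they did adjusted over the list alone (camera adjusted p = 0.483), and BLVRB (0.40) did not pass. The GYPB call was lost without wild type replicate 1 (then 1.24, and 2.96 without wild type replicate 2), and those of BLVRA and SLC25A37 were lost without knockout replicate 1 or either wild type replicate.

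The ER stress list was lower in footprints too, with a median of -0.79 and 10 of 22 genes called (14 adjusted over the list alone; camera adjusted p = 4.77e-09; adjusted p = 0.459 with an estimated correlation). The ER chaperone calreticulin CALR fell by 1.08 (SE 0.16), PDIA6 by 1.21 (SE 0.17), PDIA4 by 1.11 (SE 0.18) and PDIA3 by 1.24 (SE 0.24), the last not called without wild type replicate 1. Of 8 megakaryocyte genes 2 fell, ITGA2B (-1.80) and GP6 (-0.93), and 5 did adjusted over the list alone (median -0.88, camera adjusted p = 0.00172; adjusted p = 0.553 with an estimated correlation). Of 8 granulocyte and monocyte genes CD33 (-1.63), FCGR2A (-1.43) and LYZ (-1.89) fell, and 5 did adjusted over the list alone (median -1.27, camera adjusted p = 0.00842; adjusted p = 0.553 with an estimated correlation). SPI1 (-1.11), GP1BB (-0.57) and SRGN (-0.84) did not pass. GP6 lost its call without knockout replicate 1 or either wild type replicate, and LYZ, at -3.92 without knockout replicate 1, without knockout replicate 2 or either wild type replicate.

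Ribosomal protein footprints had a median of 0.21, with 4 of 69 genes up and 2 down (7 and 2 adjusted over the list alone; camera adjusted p = 0.00842; adjusted p = 0.660 with an estimated correlation). RPS19 (0.68) and RPL35A (0.60) rose, and RPLP2 (-0.83) and RPS13 (-0.55), both on the lower segment of chromosome 11, fell. Of 31 mitosis genes CDK1 rose (0.64), and 0 did adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0156; adjusted p = 0.660 with an estimated correlation) and with CENPF (0.54), CENPE (0.53) and KIF23 (0.59) not past the test. Of 7 mitochondrially encoded genes 0 were called by edgeR over all genes or adjusted over the list alone. Their median was 0.76 (camera adjusted p = 0.00969, and 0.660 with an estimated correlation), with values of 1.35 for MT-CO3, 1.16 for MT-ND2 and 0.51 for MT-CYB and MT-ND4. Mitochondrially encoded genes took only 0.0344% and 0.0396% of footprints in knockout and 0.0228% and 0.0239% in wild type. MT-CO3 had 24 and 18 footprint counts in knockout and 6 and 13 in wild type, while MT-CYB had 179 and 112 against 144 and 98. The ribosomal protein difference from other genes, 0.19, went to 0.037 without knockout replicate 1 (adjusted p = 0.843), 0.084 without wild type replicate 2 (0.641) and 0.30 without knockout replicate 2. The mitosis difference, 0.15, was 0.21 and 0.19 without the first 2 of these libraries, with the call lost (0.190 and 0.0946). The mitochondrial difference, 0.61, was 0.48 without knockout replicate 2, with the call lost (0.0690), and 0.93 without knockout replicate 1. RPL35A lost its call without either wild type replicate, RPS13 without either wild type replicate or knockout replicate 2, and CDK1 without knockout replicate 1 or either wild type replicate.

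RNA and footprint changes went together across genes. Over 8821 genes tested in both assays the log2 fold changes had a Pearson correlation of 0.667 and a Spearman correlation of 0.588, which describe genes and not independent replicates. Of 1633 RNA calls and 466 footprint calls among them, 365 were shared, 77 up in both and 288 down in both, and 0 were opposite. Independent lists would share 8.45 and 39.9. The assays have no library in common, but the RNA-seq titles carry the tag input and the Ribo-seq titles the tag RPF. Both may therefore come from the same cells, and the agreement need not be independent replication. Without a single Ribo-seq library the correlation lay between 0.536 (without wild type replicate 2) and 0.640.

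**Figure D3:**
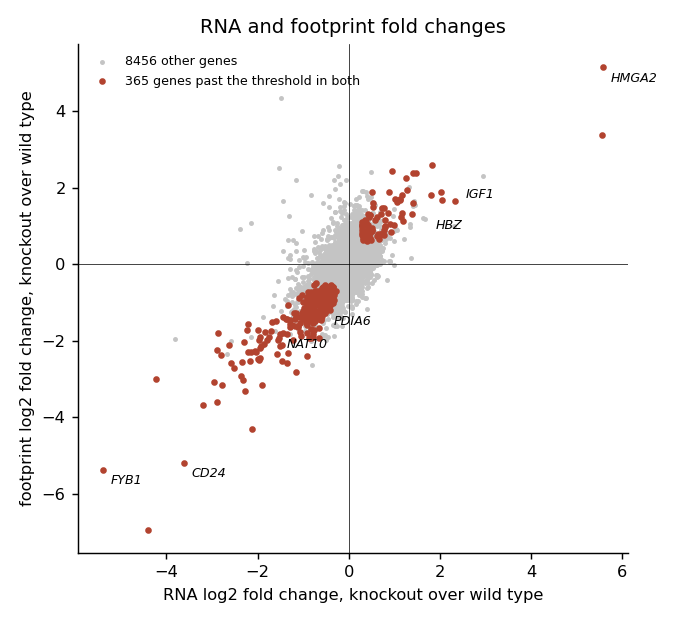
RNA log2 fold change against footprint log2 fold change (knockout minus wild type) for 8821 genes, with 365 genes called in both assays in red and the others in grey. The red points lie in the quadrants of equal sign.

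Translational efficiency, the footprint change relative to RNA, differed for 1 gene. TEDC2, a member of the tubulin epsilon and delta complex, fell by 1.42 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0390), with footprints at -1.31 (SE 0.19) and RNA at 0.07 (SE 0.10). An unadjusted p under 0.05 was reached by 877 of 8821 genes, DESeq2 called 12 genes and limma-voom 5. The limma-voom calls include TEDC2 and the DESeq2 calls do not, because the filter of DESeq2 on mean counts left TEDC2 and 5814 genes in all without an adjusted p (log2 fold change -1.40, SE 0.27, unadjusted p = 3.39e-07). The TEDC2 call was lost without RNA-seq knockout replicate 2 (adjusted p = 0.0663), without RNA-seq wild type replicate 1 (0.411) or 2 (0.992), without Ribo-seq knockout replicate 1 (0.0818) or 2 (0.0971), without Ribo-seq wild type replicate 2 (0.0554), and with TMM within each assay (0.0575) or a minimum of 10 counts (0.0950). NAT10 itself was at -0.35 (SE 0.21, edgeR adjusted p = 0.592).

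Globin efficiency had a median of -0.05 over 6 genes (camera adjusted p = 0.773), with 0 called by edgeR over all genes or adjusted over the list alone. HBZ was at -0.43 (SE 0.19), HBG1 at 0.12 (SE 0.20), HBG2 at -0.22 (SE 0.22), HBE1 at 0.91 (SE 0.47), HBQ1 at -0.32 (SE 0.18) and HBD at 0.76 (SE 0.71). The HBE1 value divides by an RNA count that is not a measure of its footprint level, and it enters the median. GATA1 (-0.11), KLF1 (-0.35), TAL1 (0.12), TFRC (-0.09) and ALAS2 (-0.35) had edgeR adjusted p values from 0.564 to 0.910. None of the other members taken by the rule passed, such as LMO2 (0.80), RHAG (-0.50), GP6 (-0.42) and HMOX2 (-0.46).

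As a list, ribosomal protein genes had a higher efficiency change, knockout minus wild type, than other genes. Their median change lay 0.43 above that of other genes (camera adjusted p = 5.20e-20, and 0.436 with an estimated correlation). Of 69 members edgeR called 0 over all genes, and 10 were up adjusted over the list alone. RPL3 was at 1.05 (SE 0.18), RPS23 at 0.84, RPS6 at 0.74 and RPS19 at 0.70. ER stress genes lay 0.33 below others (median difference -0.33, 2 of 22 down adjusted over the list alone, camera adjusted p = 5.90e-06; adjusted p = 0.320 with an estimated correlation), with PDIA6 at -0.77, HYOU1 at -0.70, CALR at -0.70 and PDIA4 at -0.55. Translation factors lay 0.12 above others (47 genes, 5 up adjusted over the list alone, camera adjusted p = 0.00170; adjusted p = 0.436 with an estimated correlation), with EIF3E at 0.66, PABPC1 at 0.58, EIF3A at 0.57 and EEF2 at 0.55. The mitochondrially encoded genes lay 0.76 above (7 genes, camera adjusted p = 0.00170, and 0.523 with an estimated correlation), with MT-CO3 at 1.61. They took at most 0.0259% of counts in any RNA-seq library and 0.0396% in any Ribo-seq library, so this difference rests on a small share of the reads. Replication histones had a difference of -0.14 (35 genes, camera adjusted p = 0.000155, and 0.323 with an estimated correlation), with H2BC13 at -0.74. Without Ribo-seq knockout replicate 1 the translation factor difference fell to 0.020, with the call lost (adjusted p = 0.0561), and the ribosomal protein difference to 0.18. The translation factor difference was also 0.032 without Ribo-seq wild type replicate 2, 0.22 without Ribo-seq knockout replicate 2 and 0.28 without Ribo-seq wild type replicate 1. The mitochondrial and histone calls were lost without Ribo-seq wild type replicate 1 (0.0707 and 0.248, the histone difference then -0.094). The mitochondrial difference was 0.48 without RNA-seq wild type replicate 1 and 1.3 without Ribo-seq knockout replicate 1.

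A further 5 lists passed camera for efficiency with differences from other genes between -0.17 and -0.06. These were mitochondrial ribosomal proteins (-0.11, adjusted p = 0.0427), amino acid stress (-0.13, 0.0481), the respiratory chain (-0.06, 0.0481), glycolysis and hypoxia (-0.14, 0.0427) and cholesterol synthesis (-0.17, 0.0429), and 0 of their members were called over all genes or adjusted over the list alone. With an estimated correlation the adjusted p = 0.610 for the respiratory chain and 0.436 for the other 4. All 5 calls were lost with RLE scaling and without Ribo-seq wild type replicate 1, among other single libraries, and without 1 library the difference of amino acid stress was as small as -0.032 (Ribo-seq wild type replicate 2), that of mitochondrial ribosomal proteins -0.054, of glycolysis and hypoxia -0.064 (both Ribo-seq wild type replicate 1) and of the respiratory chain -0.021 (Ribo-seq knockout replicate 2). SLC7A1 (-0.79), NDUFA3 (-0.70), INSIG1 (-0.65), PFKP (-0.55) and MRPL2 (-0.67) are members with values and no call.

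**Figure D4:**
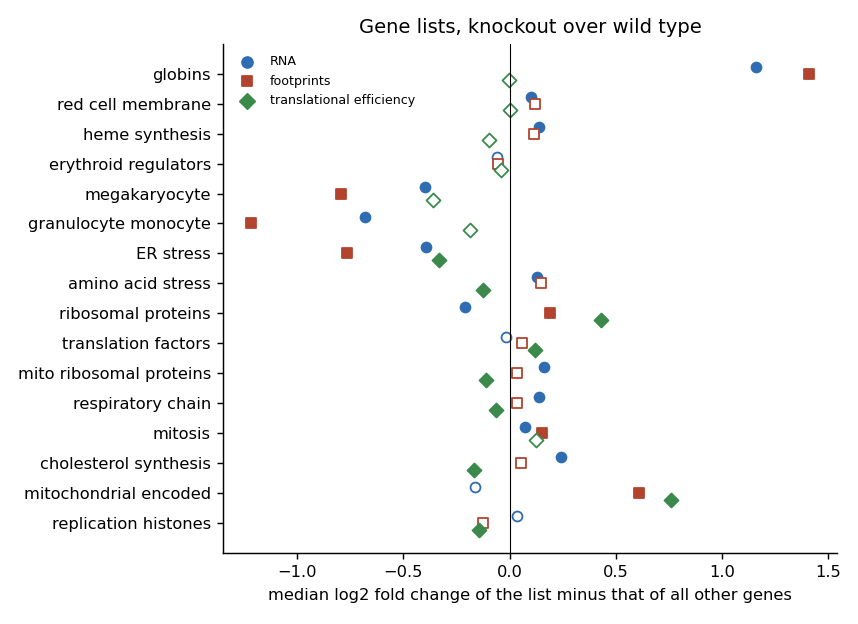
Median log2 fold change of 16 gene lists minus the median of other genes, for RNA (circles), footprints (squares) and translational efficiency (diamonds), filled where the camera adjusted p is under 0.05. Globins lie above other genes in RNA and footprints, and ER stress genes lie below in all 3 measures.

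The ac4C pull-down and its IgG control gave similar peak lists in wild type. The wild type IP list held 45290 regions on transcripts of 9649 genes and the IgG list 45426 regions of 9885 genes, and 93.3% of IP regions overlapped an IgG region, against 79.9% with random placement along the same transcripts. IP regions without an IgG region numbered 3017 (6.66%, Wilson interval 6.44 to 6.89), and IgG regions without an IP region 2934 (6.46%). In the authors' fold enrichment the IP-specific regions had a median of 2.07 and the shared regions 4.67. The knockout lists held more regions, 80709 in IP and 77342 in IgG, but shorter ones. Median lengths were 306 and 296 nt, against 632 and 623 nt in wild type. IP regions covered 42105815 nt in knockout and 43038183 nt in wild type, and IgG regions 37390506 and 42789394 nt. In knockout 16427 IP regions (20.4%, interval 20.1 to 20.6) had no IgG partner, against 9454 IgG regions (12.2%) with no IP partner. The peak lists, in which replicates are merged, allow no test between genotypes, and the knockout lists come from a set of libraries with its own protocol text.

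**Figure D5:**
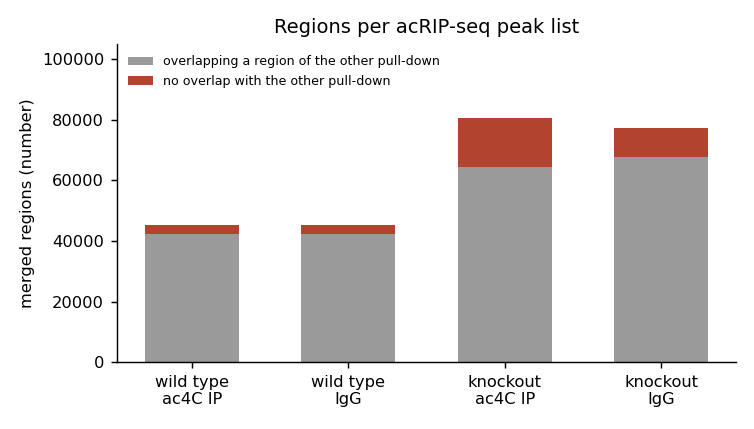
Number of peak regions in each acRIP-seq list, stacked as regions that overlap the partner list of the same genotype and regions that do not. The knockout bars reach 80709 and 77342 regions and the wild type bars 45290 and 45426.

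Of the 3017 wild type IP-specific regions, 1930 (64.0%, interval 62.2 to 65.7) overlapped no knockout IP region and were taken as NAT10-dependent, on transcripts of 1222 genes. In the IgG control 1649 of 2934 wild type IgG-only regions (56.2%, interval 54.4 to 58.0) overlapped no knockout IgG region. Of all wild type IP regions 67.7% overlapped a knockout IP region, against 62.1% with random placement along the same transcripts. For wild type IgG and knockout IgG these shares were 62.6% and 57.1%. The highest authors' fold enrichments were 6.18 in XRCC6 (ENST00000464116.2, positions 29 to 265, a retained-intron transcript) and 4.91 in PHGDH (ENST00000641939.1, positions 28 to 280, a processed transcript). SPAG7 (ENST00000575784.2, 357 to 651) and EIF3I (ENST00000677053.1, 22 to 324) carried 4.54 and 4.45 on transcripts annotated for nonsense-mediated decay, as did POLR2J3 (ENST00000489144.5, 57 to 340) with 4.27. SCAMP2 (ENST00000563829.5, 27 to 301) and MAGOHB (ENST00000537852.5, 29 to 275) carried 4.51 and 4.33 on retained-intron transcripts, and HDDC3 (ENST00000559898.5, 726 to 999) carried 4.20 on a protein-coding transcript. Positions count from 1 at the transcript's start. PHGDH fell in RNA (-0.92) and footprints (-1.07), SCAMP2 fell (-0.41) and MAGOHB rose (0.49) in RNA, and the other 5 did not pass in any fit in which they were tested. NAT10, GATA1, KLF1, TAL1, HBG1, HBG2, HBZ, HBE1, TFRC and ALAS2 had 0 IP-specific regions.

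Red cell membrane genes were frequent among genes with wild type IP-specific regions, 11 of 26 (42.3%) against 14.6% of 12435 background genes (odds ratio 4.30, two-sided Fisher's exact test, adjusted p = 0.0175). The 11 were ANK1, EPB41, GYPB, RHD, ERMAP, ADD1, ADD2, DMTN, CD47, CD59 and SLC2A1, listed because the count rests on them. Of all 1918 genes with an IP-specific region, list members or not, 215 had no wild type IgG region on any transcript. For NAT10-dependent regions the count was 8 of 26 (30.8% against 9.55%, Fisher's exact adjusted p = 0.0329), and ribosomal protein genes had 0 of 79 (Fisher's exact adjusted p = 0.0217). In the matching IgG sets the red cell membrane list had 6 of 26 and 4 of 26, with Fisher's exact adjusted p values of 0.843 and 0.986. With at least 4-fold enrichment in all lists the red cell membrane counts were 4 and 3 of 26 (adjusted p = 0.340 and 0.555), and with a -log10 q of at least 5 in all lists 10 and 7 of 26 (0.0527 and 0.176). With that q on the IP list alone they were 10 and 6 of 26 (0.00739 and 0.124). The ribosomal protein count of 0 had an adjusted p = 0.0138 with the stricter q in all lists, 0.124 with it on the IP list alone, 0.200 with the fold in all lists and 0.0630 with all RNA-tested genes as background.

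Genes with NAT10-dependent regions did not differ from other genes by camera in any fit. Their median log2 fold change was -0.01 in RNA (1187 genes, adjusted p = 0.329), -0.06 in footprints (1049 genes, adjusted p = 0.283) and -0.09 in translational efficiency (1046 genes, adjusted p = 0.30). Relative to other genes these were -0.02, -0.07 and -0.05. As a description, the medians lay at percentiles 0.43, 0.01 and 0.02 of 10000 random sets matched on expression, while those of the matching IgG set lay at 72.6, 53.2 and 77.0. The whole IP-specific set, chosen without regard to knockout regions, also lay low, at 0.17, 0 and 2.29.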

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

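Alternatives chosen only after the data were seen were the fits with the knockout RNA-seq libraries kept apart (with or without the replicate block), the fit of protein-coding genes alone, the stricter threshold on the IP list alone, the same peak alternatives for knockout, the stricter thresholds in all lists for gene lists, and removal of single libraries from the correlation of RNA and footprints. The cause of the changes below was not tested unless stated. To look for pairing, the deviations of each library from its genotype mean were correlated over genes between same-numbered libraries. Between knockout and wild type these correlations of deviations were 0.231 in Ribo-seq and -0.02 in RNA-seq. Between RNA-seq and Ribo-seq they were -0.01 in knockout and -0.23 in wild type. With these and 2 replicate numbers, the main fits did not pair libraries by number. The Ribo-seq value leaves a replicate effect shared by the genotypes possible in that assay. The rule of no overlap for efficiency did divide wild type footprints by RNA of the same number.

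The 2271 RNA calls became 1039 with DESeq2, 3513 without a filter (1925 up, 1588 down), 629 at an absolute log2 fold change of at least 1, 5476 with the knockout libraries kept apart, 3478 for protein-coding genes alone, and 2077 to 2116 without a single knockout library. Without a wild type library the RNA fit had no residual degrees of freedom and gave values with no test. The 475 footprint calls became 181 with DESeq2, 889 without a filter, 262 at the minimum fold change, and 264 to 716 without a single library. The 1 efficiency call became 12 with DESeq2, 5 with limma-voom, 0 with TMM within each assay, 81 without a filter, 0 with at least 10 counts in every library, 17 with knockout libraries kept apart, and 0 to 6 without a single library. Fewer genes pass a minimum fold by construction. A replicate block gave 1594 footprint calls, and with the knockout libraries kept apart 4983 RNA and 6 efficiency calls, the planned block of the summed RNA sample being not run because that sample has no number.

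Called lists numbered 14 in RNA, 7 in footprints and 10 in efficiency. With an estimated correlation they numbered 0, 0 and 0, and with fry 1, 0 and 0. Camera with an estimated correlation had 1, 2 and 3 degrees of freedom, so few lists could pass. In RNA its lowest unadjusted p was 0.105, and these lost calls decide little. For efficiency RLE scaling gave 5, knockout libraries kept apart 5, and the replicate block with them kept apart 5. Single libraries left out gave 12 to 14, 5 to 8 and 5 to 9, newly called lists included. Without Ribo-seq wild type replicate 1, 3 of the 10 efficiency calls stayed. Respiratory chain efficiency had a median difference of -0.137 to -0.021 without a single library, and of -0.03 without Ribo-seq wild type replicate 1, where camera's direction turned (adjusted p = 0.987).

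Of wild type IP regions, 5.36% lacked an IgG region at 4-fold enrichment, 12.2% at a reciprocal overlap of 50%, and 4.58% and 0.0986% with the stricter q or fold on the IP list alone. For knockout these were 15.6%, 33.7%, 14.8% and 5.24%, and 20.8% at the stricter q in both lists. The NAT10-dependent share was 67.9% at the stricter q, 66.8% at 4-fold enrichment, 82.4% at the reciprocal overlap and 41.7% with the fold on the IP list alone. The 1 list called among IP-specific genes became 0 with the fold on the IP list alone and 0 with the stricter q or fold in all lists. The 2 called among NAT10-dependent genes became 0 with either on the IP list alone, 1 with the q and 0 with the fold in all lists, and 1 with all RNA-tested genes as background. With the fold on the IP list alone 22 and 10 genes were left, so the red cell membrane value of 0% in both sets says little. The RNA median of these 10 genes lay 0.014 above other genes. For the 9 of them tested in footprints and efficiency the difference was -0.123 and -0.145 (camera adjusted p = 0.123 for each). The correlation of RNA and footprints was 0.691 for genes with a mean log2 CPM of at least 3, and 0.536 to 0.664 without a single library.

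Among 972 values of named genes in RNA, 890 kept direction and side of the threshold, 58 lost and 24 gained a call. In footprints 624 of 716 did, 58 lost and 32 gained a call, and 2 changed sign with no call. In efficiency 1085 of 1141 did, 8 lost and 30 gained a call, and 18 changed sign with no call. Of simulated 1.5-fold changes 44.8% were recovered in RNA, 13.4% in footprints and 14.9% in efficiency. Depth, dispersion and sample number differ between these fits, and depth alone was not varied. The simulated counts had no gene-specific dispersion beyond the trend, so these shares may be optimistic.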

Other observations

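Tests chosen only after the result was seen were those of globin shares, of windows without chromosome 11, of the chromosome 11 step, of a single wild type library, of footprints on the tip side and of the peak lists. Genes named in this paragraph and the next were chosen after their values were seen. Of 17 p53 target genes 5 rose and 3 fell in RNA (5 and 3 adjusted over the list alone; camera adjusted p = 0.110), in a line known to lack functional p53. The cell cycle inhibitor CDKN1A rose by 1.06 on the log2 scale (SE 0.10), GADD45A by 0.65 and MDM2 by 0.50, while FDXR fell by 1.07, and GADD45A (0.78) and FDXR (-1.39) also passed in footprints. Of 30 ABL and JAK signalling genes 4 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.804), with the feedback inhibitor SOCS2 up by 0.77 and the kinase JAK2 by 0.51. Of 28 apoptosis genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.844), with BCL2 at -0.85. Of 23 heat shock genes 4 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.218), with HSP90AA1 at 0.60 and HSPA8 at -0.46. Of 23 interferon response genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0756), with IFITM2, on the tip side of NAT10, at -1.68 in RNA and -1.50 in footprints.

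Translation factors went both ways in RNA, with 4 of 49 up and 11 down (5 and 13 adjusted over the list alone; camera adjusted p = 0.436), and EEF2 (-0.67) and EIF4B (-0.78) fell, as did EIF3F (-1.0) and EIF3M (-0.73), which lie on the tip side of NAT10. Of 64 ribosome biogenesis genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.101), and of 22 tRNA synthetases 2 fell (2 adjusted over the list alone; camera adjusted p = 0.90). Of 32 S phase genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.767), with CDT1 at -0.73 and RRM1, on the tip side of NAT10, at -0.87. Of 28 glycolysis and hypoxia genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.297), and of 37 replication histones 1 rose (1 adjusted over the list alone; camera adjusted p = 0.297). Of 6 stem and progenitor genes HMGA2 rose and HOXA10 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.243). Of 13 mitochondrially encoded RNAs edgeR called 0, over all genes or adjusted over the list alone (camera adjusted p = 0.318), and their median was -0.36 against wild type replicate 1 and 0.03 against wild type replicate 2.

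The RNA of 6 globin genes rose in knockout while GATA1 fell. A gain of copies of either globin segment argues for higher neighbours, but the 20 nearest tested neighbours of the alpha cluster had a median log2 fold change of -0.14 (SE 0.13) and those of the beta cluster -0.81 (SE 0.13), with 17 of the latter 20 lower. A scaling artefact is excluded by the raw counts, whose shares no scaling factor changes. The lowest knockout share of globins was 2.18 times the highest wild type share. A difference of genotype, of clone or of culture state may explain the rise, and with 1 summed knockout RNA sample and no second clone named these were not tested against each other.

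Changed genes lay in a run of neighbours that ended at NAT10. The spread of medians over windows of 50 genes was 1.69 times the highest of 100 shuffled gene orders, as changed copy number would give. This rests mostly on chromosome 11, which holds all 4 of 231 windows below the shuffled range, while 2 windows lay above it. Without that chromosome the spread was 1.196 times the highest shuffled one. The point that best split chromosome 11 lay 0 tested genes from NAT10, between CAPRIN1 and ABTB2 (100 bootstrap draws, -4 to 24 genes), or 9 genes away in footprints. A single deviating wild type library is excluded by the median of -0.57 on the tip side against the less distant of the wild type libraries, and an artefact of RNA-seq alone by the footprint median of -0.60. A candidate explanation is loss of a copy of the chromosome segment from the edited site to the tip. Loss of 1 of 3 copies gives a log2 ratio of -0.58 at equal expression per copy, but the number 3 was assumed after the median was seen and was not measured. No DNA data were used here, so this stays an untested hypothesis, under which lower expression of these 173 genes could not be assigned to loss of NAT10 activity.

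IP and IgG lists overlapped widely within a genotype and held more, shorter regions in knockout. Weak regions near the threshold may account for the wild type IP-specific regions, since 83.9% of them lay in the lowest of 4 equal bins of fold enrichment, and sampling differences between alike libraries would give the ratio of 1.03 between IP-only and IgG-only regions in wild type. In knockout that ratio was 1.74, which excludes equal sampling of alike libraries there and leaves open what made the knockout IP list hold more regions of its own. An effect on the ac4C pull-down alone is excluded as the whole reason for the higher number of knockout regions. That number was 1.70 times the wild type one in IgG and 1.78 times in IP. A difference between the library sets shared by IP and IgG fits these values, with the excess in IgG being 89.8% of that in IP. A loss of ac4C in knockout stays open, since library set and genotype coincide and depth was not given.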
